A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

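Lariat sequencing libraries from 5 strains of Saccharomyces cerevisiae lacking DBR1 were compared. Per the labels' protocols, total RNA was depleted of ribosomal RNA and treated with RNase R, which digests linear RNA. Per the submitters' processing notes, Trimmomatic and Bowtie2 were used with build R64, whose versions are not given in the sources used here. The deposited files give counts of filtered reads that span a branch point, per pair of 5' splice site and branch point and per annotated intron. Per the file headers, annotated counts include branch points within 2 nt of the annotated one, and aberrant 5' splice sites lie more than 5 and less than 1000 nt from the annotated one and join the annotated branch point within 2 nt. The authors also deposited a rate table for 13 introns as fractions of aberrant over aberrant plus annotated reads. Another 55 columns of per-sample values, for single aberrant sites and for annotated counts in the rate table, were not used.

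Groups were taken from the labels. The 2 technical libraries of the second prp8-N1869D sample were summed and count as 1 sample. Annotated counts equalled the sum over matching pairs in 280 of 280 introns. Aberrant counts equalled the recomputed ones in 183 of 183 introns in PRP8-WT and 182 of 183 in prp8-V1860N, with 154 of 155, 173 of 174 and 172 of 174 in prp8-N1869D, prp8-V1870N and prp8-V1860D. Positions matched the reference of build R64 used here: 279 of 280 annotated introns began with GT and 279 of 280 branch points were A. Positions are counted from 1.

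All other pairs were called unannotated. They were divided into pairs sharing an end with an annotated intron, mirror images (opposite strand, ends swapped, within 10 nt), mitochondrial pairs and the rest, which were placed by the reference annotation. The sources used here do not say how strand was assigned. The aberrant activation rate was the sum of unannotated reads over annotated reads, as fixed before the data were examined. The narrower rate of the file headers was added as a second measure after seeing the files, and ratios per gene, lists and named genes use that narrower definition. Shares of annotated reads were compared as log2 ratios with a pseudocount of 0.5 reads. Sites were thinned to 652680 reads by the hypergeometric expectation. List medians were placed among 10000 random lists of the same size matched on mean count in 10 classes, and for aberrant ratios only introns with at least 10 annotated reads in every library were used. PRP8-WT and 3 of the 4 mutants have 1 library each, and no tests between strains were made for any mutant.

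The named genes followed a rule fixed in advance: per mutant the 6 highest and 4 lowest aberrant ratios among genes with at least 20 reads over both libraries, the 10 genes with the most aberrant reads, the 5 introns with the most reads, the 5 highest and 5 lowest share ratios among introns with at least 50 reads over both libraries, and 2 members of each list. RPL16B and RPL28 were named after their values were seen.

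Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for alternative size factors of the counts only. The calculations were tested on simulated data, where aberrant ratios made 4-fold higher, a true log2 of 2, came out at a median of 1.96 over 92 introns, unaltered ones at 0.08 over 27, and thinning gave 99.98% of the sites of 20 random draws. Library depth ranged from 652680 to 3517283 reads, a ratio of 5.39. Alternatives covered minimum reads per site, denominators, genes with the most reads, distance to annotated introns, scaling, pseudocounts, scales of correlation, matching of sites and leaving out each technical library. Others were chosen after seeing the data: leaving out mirror images, leaving out distant and mitochondrial pairs, leaving out the 5 introns with the most aberrant reads, a minimum of 20 aberrant reads per gene and per intron of a list, leaving out the RPS21B position from the GT share, thinning of the library searched for shared sites, all alternatives for the narrower rate, and leaving out each technical library for site numbers, locations, sequences and ratios per gene.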

Results

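Lariat sequencing was used to map where the spliceosome of Saccharomyces cerevisiae had carried out branching in a strain with wild-type PRP8 and in 4 strains with a mutation in the RNaseH domain of Prp8, a protein at the core of the spliceosome. The mutants were prp8-V1860N, prp8-V1860D, prp8-N1869D and prp8-V1870N. All strains lacked DBR1, the gene of the debranching enzyme, so that excised introns were kept as lariats, and each read pair counted joined a 5' splice site to a branch point. There was 1 library per strain, and for prp8-N1869D also a second biological sample sequenced as 2 technical libraries, which were summed and treated as 1 sample. Only prp8-N1869D therefore has a replicate check, against a single PRP8-WT library, and differences of the other mutants from PRP8-WT have none. The difference between the 2 prp8-N1869D samples is the only measure of spread between samples. PRP8-WT had 3517283 lariat reads, prp8-V1860N 2288752, prp8-V1860D 2174942, prp8-V1870N 1931509 and prp8-N1869D 1222720. The technical libraries had 713781 and 652680 reads. The table listed 174421 distinct pairs of 5' splice site and branch point, of which 69.0% had a single read over the 7 libraries, and 280 annotated introns of 270 genes. Intervals are exact binomial 95% intervals and cover counting error only.

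The first comparison asked how many lariat reads in each strain matched no annotated pair of 5' splice site and branch point. Such reads include mirror images of annotated introns on the opposite strand, 5.76% of all lariat reads in PRP8-WT, and pairs within 5 nt of an annotated 5' splice site, 1.08%. Part of both may come from annotated lariats. For mirror images, the sources used here do not say how strand was assigned. The pairs within 5 nt lie on the strand of the annotated intron and join its branch point within 2 nt. Unannotated lariats took a larger share of reads in every mutant library than in PRP8-WT, most in prp8-V1870N and prp8-N1869D and less in prp8-V1860N and prp8-V1860D. They made up 13.5% of reads in PRP8-WT (13.46 to 13.53), 14.8% in prp8-V1860N (14.76 to 14.85), 15.3% in prp8-V1860D (15.26 to 15.35), 18.8% in prp8-N1869D (18.71 to 18.85) and 19.7% in prp8-V1870N (19.69 to 19.80). As reads per annotated read, the fold over PRP8-WT was 1.11 in prp8-V1860N, 1.16 in prp8-V1860D, 1.48 in prp8-N1869D and 1.58 in prp8-V1870N. The second prp8-N1869D sample gave 1.51, which is 1.02 times the first, and its technical libraries differed by 1.08 times. With lariats of introns outside ribosomal protein genes alone as denominator, a count chosen after seeing the data, the folds were 1.19 and 1.097 in the prp8-N1869D samples and 1.35 in prp8-V1870N. That fold was not computed for prp8-V1860N and prp8-V1860D, so the order of strains by it is not known. With depth made equal, the number of distinct unannotated sites followed the order of strains seen with all annotated reads as denominator. Thinned to 652680 reads, PRP8-WT had 15543 sites, prp8-V1860N 17787, prp8-V1860D 18061, prp8-N1869D 23399, its second sample 23050 and prp8-V1870N 25258, so that the second sample lay below the first by sites and above it by reads. As found, the deeper PRP8-WT library had 50246 sites and prp8-N1869D 36756.

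Reads at aberrant 5' splice sites of annotated introns, joined to the annotated branch point, gave a different order. They are the quantity the authors' tables define per intron. prp8-V1860N and prp8-V1860D lay below PRP8-WT and the other mutants above it. The rate, as a percent of aberrant plus annotated reads, was 0.419% in PRP8-WT (0.412 to 0.426), 0.395% in prp8-V1860N (0.387 to 0.404) and 0.329% in prp8-V1860D (0.321 to 0.338). It was 0.451% in prp8-N1869D (0.438 to 0.464), 0.474% in the second prp8-N1869D sample (0.462 to 0.487) and 0.446% in prp8-V1870N (0.436 to 0.457). Against PRP8-WT the folds were 0.943, 0.786, 1.08, 1.13 and 1.06 in that order, beside a fold of 1.05 between the 2 prp8-N1869D samples. The excess in both prp8-N1869D samples rested on few introns. Without the 5 introns with the most aberrant reads, an alternative chosen after seeing the data, their folds were 1.0 and 1.0. Those of prp8-V1860N, prp8-V1860D and prp8-V1870N were then 0.998, 0.835 and 1.11. With at least 5 reads per site prp8-N1869D stood at 0.998, and its second sample and prp8-V1870N at 1.02 and 1.02. With all lariat reads as denominator prp8-V1870N stood at 0.988 and the prp8-N1869D samples at 1.01 and 1.06.

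**Figure D1:**
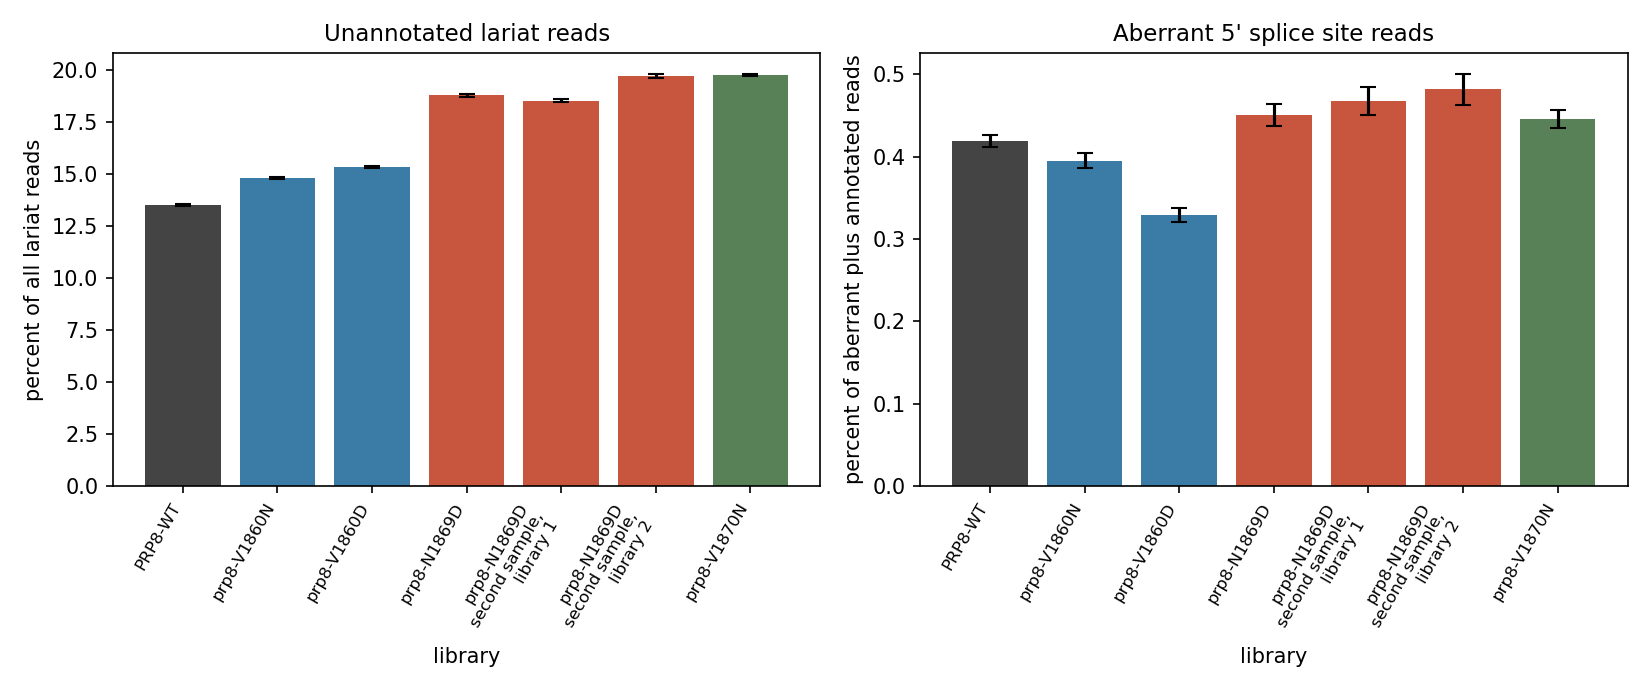
Bars give, for each of the 7 libraries, unannotated reads as a percent of all lariat reads (left) and aberrant 5' splice site reads as a percent of aberrant plus annotated reads (right), with exact binomial 95% intervals. On the left every mutant library lies above the 13.5% of PRP8-WT, while on the right prp8-V1860D lies lowest at 0.329%.

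The next comparison asked which genes carried the aberrant 5' splice sites. The 10 genes with the most such reads held 73.3% of them, and NHP6B alone, which encodes a high mobility group chromatin protein, held 17.6%. The others were the ribosomal protein genes RPL22B, RPS22B, RPS26A, RPL22A, RPS21B, RPL24B, RPL40B and RPL2B, and GCR1, a transcriptional activator of glycolytic genes. In NHP6B the aberrant share was 13.6% in PRP8-WT (13.1 to 14.2), 25.3% in prp8-N1869D (23.9 to 26.8), 24.5% in prp8-V1870N (23.3 to 25.7) and 50.2% in the second prp8-N1869D sample (48.0 to 52.4), so that the 2 prp8-N1869D samples differed from each other by at least as much as the first did from PRP8-WT. It was 12.8% in prp8-V1860N and 13.4% in prp8-V1860D. Most NHP6B reads used a GTAAGT at position 426630 on chromosome II, minus strand (build R64), 243 nt inside the annotated intron. In RPS22B intron 2, whose gene is a snoRNA host, the share was 21.1% in PRP8-WT (19.8 to 22.4) and higher in every mutant, at 34.5% in prp8-V1860N, 32.9% in prp8-V1860D, 47.6% in prp8-N1869D, 51.6% in its second sample and 31.2% in prp8-V1870N. RPS26A had 2.25% in PRP8-WT, 4.76% and 5.74% in the prp8-N1869D samples and 4.06% in prp8-V1870N. RPL24B was lower in every mutant, from 1.80% in PRP8-WT (1.69 to 1.92) to 1.06% in prp8-V1860D and 0.512% in the second prp8-N1869D sample. GCR1 had only 47 annotated reads in PRP8-WT, and its aberrant share lay between 79.7% and 90.3% across samples. A 5' splice site inside the intron makes a shorter lariat, by 243 nt in NHP6B, 414 nt in RPS22B intron 2 and 199 nt in RPS26A. Short annotated introns also took a larger share in the prp8-N1869D samples and prp8-V1870N, as given below, so lariat length may raise these aberrant shares. The main sites of RPL24B, 163 nt inside, and RPL28, 384 nt inside, went the other way, and this was not tested.

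RPS21B, a small subunit protein gene, was higher in every mutant: 1.27% in PRP8-WT (1.11 to 1.44), 3.66% in prp8-V1860N, 4.48% in prp8-V1860D, 5.02% in prp8-N1869D, 6.66% in its second sample and 5.45% in prp8-V1870N. Nearly all of these reads joined the branch region to position 157160 on chromosome X, minus strand, 89 nt inside the intron, which reads ATAAAA and has no GT. Of 1995 such reads, 1968 were placed at branch coordinate 156817, whereas most annotated RPS21B lariats, 42294 reads, were at 156816.

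In the authors' deposited table, which gives rates for 13 introns in the 5 strains, RPL16B stood at 2.98% in PRP8-WT, 2.04% in prp8-V1860N, 1.56% in prp8-V1860D, 6.16% in prp8-N1869D and 4.48% in prp8-V1870N. Recomputed from the counts, the second prp8-N1869D sample had 9.40% there (8.0 to 10.9). Of the 13 introns, 12 were lower than PRP8-WT in prp8-V1860D, 8 of them with intervals apart, and 10 were lower in prp8-V1860N, 5 with intervals apart. In prp8-N1869D 8 were higher, 6 with intervals apart, in its second sample 10 and 8, and in prp8-V1870N 9 and 5. RPL28, the gene of a large subunit protein, went the other way, with 4.19% in PRP8-WT (3.5 to 4.96) and 2.60% (1.96 to 3.37) and 2.37% (1.84 to 3.01) in the prp8-N1869D samples.

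**Figure D2:**
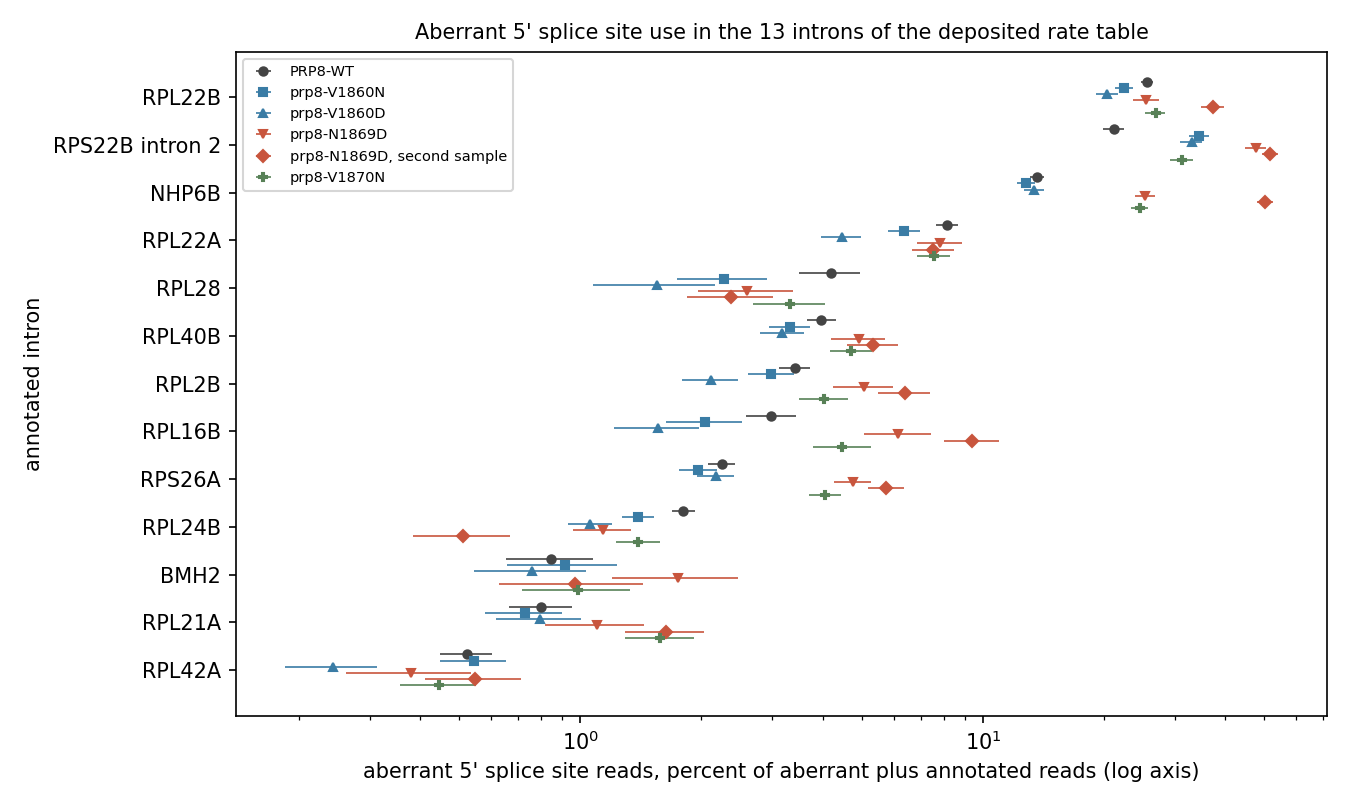
Points give aberrant 5' splice site reads as a percent of aberrant plus annotated reads on a log axis, recomputed from the counts for 13 introns and 6 samples, with exact binomial 95% intervals. RPS22B intron 2 lies above its PRP8-WT value of 21.1% in every mutant sample, and RPL24B below its value of 1.80%.

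Over the 252 genes with at least 10 annotated reads in every library, the median log2 aberrant over annotated ratio against PRP8-WT was 0.24 in prp8-V1860N, 0.17 in prp8-V1860D, 0.42 and 0.18 in the prp8-N1869D samples and 0.22 in prp8-V1870N. The direction per gene cannot be read from this set, since genes with 0 aberrant reads in both libraries count as higher where the mutant has fewer annotated reads: in prp8-V1860D 61 of the 139 higher genes were of this kind, in prp8-V1860N 57 of 153, in the prp8-N1869D samples 67 of 161 and 49 of 148, and in prp8-V1870N 52 of 150. Among the 106 genes with at least 20 aberrant reads over all libraries, a limit set after seeing the data, 39 were higher and 67 lower in prp8-V1860D with a median of -0.45, 53 and 53 in prp8-V1860N with 0.01, 60 and 46 in prp8-N1869D with 0.24, 63 and 43 in its second sample with 0.19, and 54 and 52 in prp8-V1870N with 0.07. The second prp8-N1869D sample, at 0.18 over the 252 genes, stood at 0.74 without technical library 1 and at 0.74 without library 2. Of these genes 113 had 0 aberrant reads in that sample, and their ratio rises by construction when annotated reads are fewer. Intervals lay apart from PRP8-WT in few of the 252 genes: 13 above and 4 below in prp8-N1869D, 19 and 9 in its second sample, 14 and 5 in prp8-V1870N, 8 and 11 in prp8-V1860N and 6 and 19 in prp8-V1860D.

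Among the genes at the top by size, ECM33, a cell wall protein gene, had 0.0396% aberrant reads in PRP8-WT (0.0198 to 0.0708), 0.273% in prp8-V1860N, 0.201% in prp8-V1860D, 0.520% in prp8-N1869D (0.330 to 0.779), 1.05% in its second sample and 0.994% in prp8-V1870N (0.789 to 1.24). In each mutant sample most of these reads began at 393110 on chromosome II, plus strand, which reads CTATTA and has no GT. A minus-strand pair from 393483 to 393108, close to their mirror image, had more reads, 140 in PRP8-WT and 972 in prp8-V1870N. Whether the ECM33 reads come from that pair was not tested. RPL6B had 5 aberrant reads in PRP8-WT and 96 in prp8-V1870N, or 0.0222% (0.00721 to 0.0518) against 1.34% (1.09 to 1.63). Of these, 3 and 95 began at 1027926 on chromosome XII, plus strand, with GTATAC. That position lies 943 nt upstream of the annotated 5' splice site, so these pairs are long. Distant pairs with no shared end also had more reads in prp8-V1870N than in PRP8-WT, as given below. Whether the RPL6B reads come from lariats was not tested. Other genes high on the list had few reads. YOP1, which shapes the endoplasmic reticulum, had 0 aberrant reads beside 17518 annotated ones in PRP8-WT and 5 in prp8-V1860N. SAR1 had 0 and 3, RPL13A 0 and 2, TMH18 0 and 3, and EFM5 1 and 7. In prp8-N1869D RPL40A had 3 reads, NSP1 2, and TUB3 1, all with 0 in PRP8-WT, of which the second sample had 0 for each, and RPL24A had 2 against 1. In prp8-V1870N RPS4A had 4 reads, QCR9 2 and MRK1 2, with 0 in PRP8-WT. In prp8-V1860D AIM11 had 10 against 1, YDL012C 6 against 1 and VMA10 2 against 0.

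At the low end, VMA9, a subunit gene of the vacuolar ATPase, had 0.334% in PRP8-WT (0.248 to 0.441) against 0.0374% in prp8-N1869D (0.0102 to 0.0958) and 0.0413% in its second sample. RRT8 had 59 aberrant and 58 annotated reads in PRP8-WT, or 50.4% (41.0 to 59.8), and 11.5% (4.35 to 23.4) and 8.57% (3.21 to 17.7) in the prp8-N1869D samples. TFC3, a subunit gene of transcription factor TFIIIC, had 0.553% in PRP8-WT and 0.0645% in prp8-V1870N. RPL35B had 23 aberrant reads in PRP8-WT and 0 in prp8-N1869D, but 6 in its second sample. APE2 had 11 in PRP8-WT and 0 in prp8-N1869D and prp8-V1860D, with 3 in the second prp8-N1869D sample. In prp8-V1860D RPL26A had 2 reads against 29, RPL20A 0 against 8 and RPS26B 0 against 4. In prp8-V1860N RPL17A had 0 against 8, GIM4 0 against 5, RPL2A 0 against 5 and RPL29 0 against 4, and in prp8-V1870N RPL17A and RPL20A had 0 against 8 and RPL7A 0 against 6.

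By list, many introns had 0 aberrant reads in PRP8-WT, the mutant or both, 90 of the 154 other introns in prp8-V1860D and 6 of the 10 snoRNA host introns in prp8-N1869D, so list medians are given first for introns with at least 20 aberrant reads over all libraries, a limit set after seeing the data. The 68 ribosomal protein introns had a median log2 aberrant ratio of -0.49 in prp8-V1860D, with 45 lower, at percentile 23.3 of 10000 random lists matched on mean count, and of 0.39 and 0.39 in the prp8-N1869D samples, with 43 and 49 higher (percentiles 61.6 and 91.7). The 38 other introns stood at -0.26 in prp8-V1860D, with 24 lower, at percentile 92.1, which is high among the random lists. In the prp8-N1869D samples they stood at -0.60 and -1.097, with 22 and 23 lower (percentiles 0.365 and 0.060). The 9 introns of genes with 2 introns had -1.32 and -1.58 in the prp8-N1869D samples, with 8 and 6 lower (percentiles 0.210 and 1.48), but the summed reads of the whole list were 1.82% aberrant in both samples and 1.34% in PRP8-WT, the opposite direction. The 4 snoRNA host introns had 0.01 in prp8-N1869D and 1.003 in its second sample, with 2 and 4 higher. Without the limit of 20 reads, the medians were -0.44 for ribosomal protein introns and 0.44 for other introns in prp8-V1860D, and in the prp8-N1869D samples 0.42 and 0.05 for other introns, -0.63 and -0.82 for genes with 2 introns and 1.13 and 1.29 for snoRNA host introns, values that rest in part on introns without aberrant reads. The meiotic list had 0 introns with 20 aberrant reads and the ubiquitin and protein turnover list 1, and the actin and cytoskeleton list had 3 and the RNA and ribosome biogenesis list 6.

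The design also asked where in the genome unannotated lariats lay. In PRP8-WT 12.1% of unannotated sites shared an end with an annotated intron, 5.71% were its mirror image on the opposite strand, 14.3% lay elsewhere in intron-containing genes, 9.51% in genes without introns, 34.2% antisense to genes, 17.3% between genes, 3.98% in RNA genes or transposons and 2.88% in mitochondrial DNA. By reads the mirror images led with 42.7%, at 6.66 per 100 annotated reads in PRP8-WT and between 6.76 and 7.46 in the mutant samples. Genes without introns took 10.1% of sites in prp8-V1860N (9.86 to 10.4) and in prp8-V1860D (9.82 to 10.4), 13.3% in prp8-N1869D (12.98 to 13.68), 14.2% in its second sample and 14.4% in prp8-V1870N (14.1 to 14.7). Pairs with no shared end and over 1000 nt apart had 1.34 reads per 100 annotated reads in PRP8-WT, 2.34 in prp8-V1860N, 3.11 in prp8-V1860D, 4.77 in prp8-N1869D, 4.95 in its second sample and 6.67 in prp8-V1870N. In these the branch base was A in 32.5% of reads in PRP8-WT (32.0 to 32.9) and 30.0% in prp8-V1870N, while in pairs of up to 200 nt it was A in 68.6% and 72.7%. Among 20 glycolytic and other abundant genes without introns, PRP8-WT had 245 reads at 154 sites, or 0.805 per 10000 annotated reads. The value was 0.856 in prp8-V1860N, 0.706 in prp8-V1860D, 1.54 and 0.977 in the prp8-N1869D samples and 1.46 in prp8-V1870N. PDC1, the gene of pyruvate decarboxylase, had the most with 68 reads in PRP8-WT, followed by TDH3 of glycolysis with 46.

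Aberrant 5' splice sites lay mostly inside the intron. In PRP8-WT 65.4% of 826 sites (62.0 to 68.6) and 91.2% of reads lay downstream of the annotated 5' splice site, and the share of sites was 55.5% in prp8-V1860D (51.4 to 59.5), 60.8% in prp8-V1860N, 67.3% and 68.7% in the prp8-N1869D samples and 62.7% in prp8-V1870N. The sequences were weaker matches to the annotated pattern. GT opened 83.8% of aberrant sites in PRP8-WT (81.1 to 86.2), 86.3% in prp8-N1869D (82.9 to 89.2), 88.4% in its second sample (85.3 to 91.1) and 83.5% in prp8-V1860D (80.2 to 86.4), intervals that overlap. By reads the GT share was 96.3% in PRP8-WT, 94.2% in prp8-N1869D and 93.4% in the second sample, 92.8% in prp8-V1860N, 88.3% in prp8-V1860D and 90.3% in prp8-V1870N, below PRP8-WT in each, while by sites prp8-N1869D, its second sample and prp8-V1860N lay above it. Most of the difference by reads came from the RPS21B position at 157160, which held 547 of 714 reads without GT in prp8-V1860D and 208 of 471 in PRP8-WT. Without that position, an alternative chosen after seeing the data, the GT share by reads was 97.9% in PRP8-WT (97.6 to 98.2), 97.8% in prp8-V1860N, 97.0% in prp8-V1860D (96.5 to 97.4), 97.6% and 97.7% in the prp8-N1869D samples and 96.7% in prp8-V1870N (96.2 to 97.1). G at position 5 was present at 39.8% of aberrant sites in PRP8-WT and 42.3% in prp8-N1869D, against 99.9% of annotated pairs in both. A at position 3 was present at 62.1% and 65.3%, and T at position 6 at 40.4% and 37.1%. T at position 4 was present at 45.0% and 45.6% of aberrant sites, against 86.2% of annotated pairs in PRP8-WT. The branch base was A at 77.7% of aberrant sites in PRP8-WT and 78.4% in prp8-N1869D, against 54.9% and 54.5% of annotated pairs. Both classes join an annotated branch point within 2 nt by definition, so these shares do not describe an independent choice of branch base. GT was also frequent in other unannotated pairs. It opened 55.3% of mirror images in PRP8-WT and 59.7% in prp8-N1869D. By definition these begin within 10 nt of an annotated branch point, on the opposite strand. The sequence of that region limits their bases, so this share cannot decide whether calling favoured GT. In PRP8-WT GT opened 81.1% of reads in pairs with no shared end over 1000 nt apart, but 12.4% of pairs within 5 nt of an annotated 5' splice site. Whether the calling of pairs favoured GT was not tested, so the GT share alone does not mark splicing.

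Lariats of annotated introns were compared next. In the prp8-N1869D samples and in prp8-V1870N, short introns outside ribosomal protein genes took a larger share of annotated reads than in PRP8-WT. The 104 ribosomal protein introns held 67.5% of annotated reads in PRP8-WT, 66.8% in prp8-V1860N, 65.7% in prp8-V1860D, 62.0% in prp8-V1870N, 59.4% in prp8-N1869D and 55.2% in its second sample. Their median log2 ratio over PRP8-WT was -0.35 and -0.34 in the prp8-N1869D samples, with 76 and 87 lower, and -0.17 in prp8-V1870N. The 176 other introns had medians of 0.88, 1.06 and 0.52, with 150, 143 and 138 higher. In prp8-V1860N the medians were -0.03 and 0.18 and in prp8-V1860D -0.08 and 0.13, where that of ribosomal protein introns was 0.01 with size factors of the median-of-ratios type. The list of other introns stood at percentile 100 in all 5 mutant samples and ribosomal protein introns at percentile 4.29 or below. Together both lists hold all 280 introns, so their percentiles state a single result. Random lists of 176 introns share most of their members, so small shifts give extreme percentiles. Such lists stood at 0.75 and 0.74 in the prp8-N1869D samples, 0.37 in prp8-V1870N, 0.11 in prp8-V1860N and 0.06 in prp8-V1860D. The median over all 280 introns was 0.41 in prp8-N1869D, 0.29 in its second sample and 0.19 in prp8-V1870N on this scale and 0.11, 0.02 and 0.07 with those size factors. The gap between both groups, which no scaling alters, was 1.23, 1.40 and 0.69.

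The groups differed in length, with medians of 367.5 nt between 5' splice site and branch point for ribosomal protein introns and 64 nt for the others, and no ribosomal protein intron was below 100 nt. The 134 other introns below 100 nt had a median of 1.07 in prp8-N1869D and 1.30 in its second sample, while the 18 of 200 to 500 nt had -0.58 and -0.61, below the -0.35 and -0.35 of the 97 ribosomal protein introns of that length. At 500 to 2000 nt the 5 other introns had -0.19 and 0.12, above the -0.53 and -0.28 of 4 ribosomal protein introns.

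**Figure D3:**
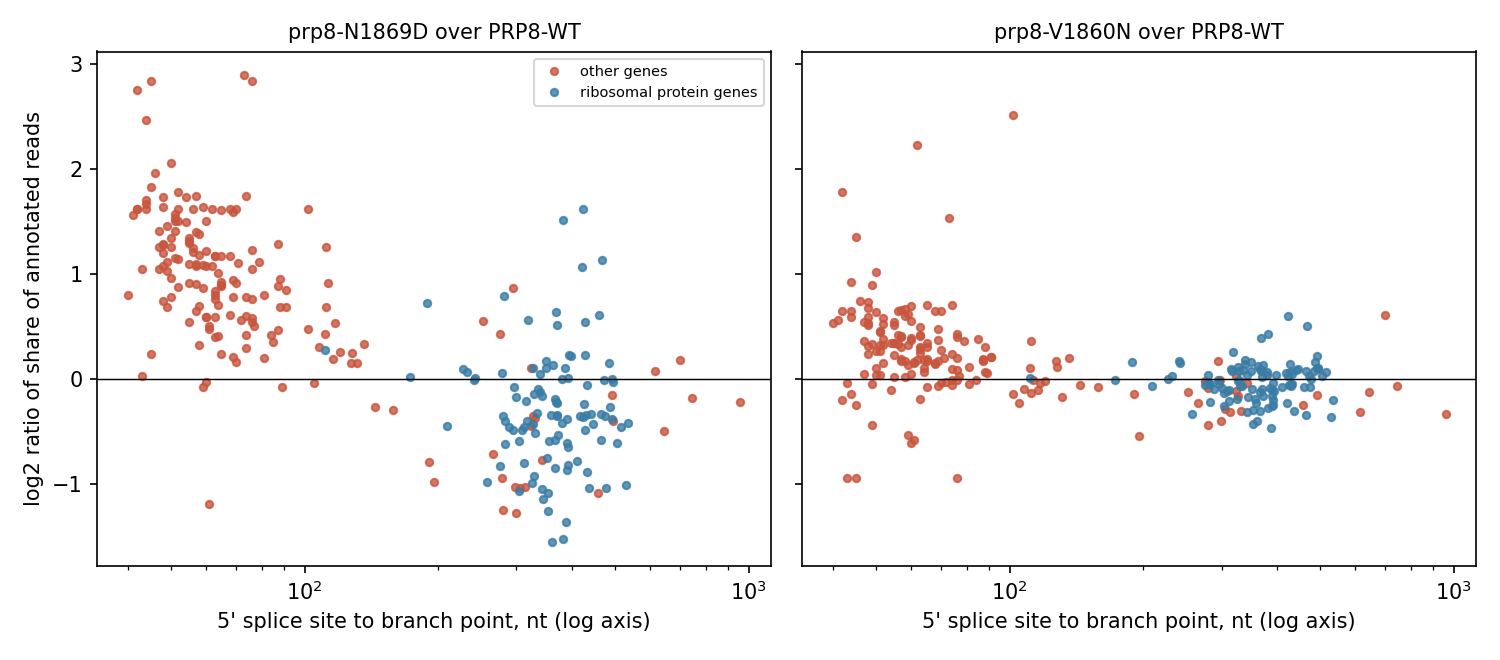
Each point is 1 annotated intron, with the distance from 5' splice site to branch point in nt on a log axis and the log2 ratio of its share of annotated reads over PRP8-WT, for prp8-N1869D (left) and prp8-V1860N (right). The 134 other introns below 100 nt have a median of 1.07 on the left and 0.29 on the right.

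The introns with the highest ratios were short. In prp8-N1869D they were YCL002C at 2.47, IAI11 at 2.05, COF1, the gene of cofilin, at 1.96, APS3 at 1.78 and YML6 at 1.74, and in its second sample 2.47, 1.44, 2.48, 1.76 and 1.82. In prp8-V1870N they were BIG1 at 1.86, ATG38 at 1.71, YCL002C at 1.70, VMA9 intron 1 at 1.39 and YNL050C at 1.29. BIG1, ATG38, REC114, YCL002C and YBR062C led in prp8-V1860D at 1.43, 1.04, 0.98, 0.97 and 0.95, and IAI11, CIN2, COF1, ATG38 and YML6 in prp8-V1860N at 1.02, 0.92, 0.74, 0.73 and 0.70. The lowest in prp8-N1869D were RPS18B at -1.56, RPS9B at -1.53, RPL20B at -1.36, COX4, the gene of a cytochrome c oxidase subunit, at -1.28 and RPL37B at -1.26, with -2.04, -1.72, -1.46, -2.21 and -1.08 in the second sample. In prp8-V1870N QCR9 of respiratory complex III was at -1.39, COX4 at -1.27, RPS18B at -0.93, RPS9B at -0.89 and RPS14A at -0.85. NCE101, PSP2, PTC7, RPL20B and STO1 were lowest in prp8-V1860N at -0.61, -0.54, -0.53, -0.47 and -0.44, and PTC7, RCF3, MPT5, QCR9 and NOG2 in prp8-V1860D at -0.84, -0.80, -0.73, -0.70 and -0.64.

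The 5 introns with the most reads were those of snR17a, which encodes the U3 snoRNA, RPS30B, RPS24A, PRE3 and RPL2A. snR17a took 6.63% of annotated reads in PRP8-WT and 5.52% and 4.15% in the prp8-N1869D samples. RPS24A, a ribosomal protein intron, went against its group, with 1.47% in PRP8-WT, 4.50% and 5.77% in the prp8-N1869D samples and 3.20% in prp8-V1870N. PRE3, a gene of a proteasome core subunit, took 1.78%, 3.09%, 4.11% and 3.35% in the same order. RPS30B was at 3.999% in PRP8-WT, 3.41% in prp8-N1869D and 1.59% in its second sample, and RPL2A at 2.41%, 2.91% and 1.96%.

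Of the remaining lists, all 12 measured introns of the meiotic list were higher in prp8-N1869D, with a median of 1.42 at percentile 65.1, and 9 were in the second sample, with 1.33 at percentile 49.5. REC114 and REC107, genes of meiotic recombination, stood at 1.11 and 0.93. snoRNA host introns had medians of 0.23 and 0.11 in the prp8-N1869D samples, at percentiles 21.7 and 19.2, with -0.02 for the second sample without technical library 2, and -0.24 in prp8-V1860D at percentile 3.43, -0.09 in prp8-V1860N at 3.15 and -0.13 in prp8-V1870N at 4.96, with TEF4 at 0.42 and RPL7B intron 1 at 0.10 in prp8-N1869D. Genes with 2 introns had 0.80 and 0.76 (percentiles 74.9 and 67.5), the second sample standing at 1.24 without technical library 1, with YOS1 intron 1 at 0.32 and VMA9 intron 2 at 1.17. The actin and cytoskeleton list had 0.60 and 0.99 (65.8 and 76.7), with ARP2 at 0.31 and ACT1 at -0.72. The RNA and ribosome biogenesis list had 0.59 and 0.73 (31.7 and 49.9), with LSM7 at 0.50 and ECM33 at -1.04. The ubiquitin and protein turnover list had 0.80 and 1.08 (61.7 and 77.8), with PRE3 at 0.79 and UBC4 at 0.78. In prp8-V1870N the medians were 1.07 for the meiotic list (91.7), 0.57 for genes with 2 introns (89.3), 0.20 for the actin list (40.3), 0.33 for the biogenesis list (43.9) and 0.42 for the ubiquitin list (66.1).

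Reproducibility was measured on the prp8-N1869D libraries. Counts per annotated intron had a Pearson correlation of 0.993 between the technical libraries on the log2 scale and of 0.989 and 0.988 between each and the first sample, across introns, which are not independent replicates. Across all pairs the values were 0.733, 0.734 and 0.718 and Spearman's rho was -0.12, -0.09 and -0.13, since most pairs had reads in a single library. For unannotated pairs alone r was 0.502 between technical libraries. The technical libraries differed by more than counting error, with a chi-square per degree of freedom of 28.4 over introns, against 109 and 111 between each and the first sample and 548 between PRP8-WT and prp8-N1869D. Chi-square grows with depth, which differs between these pairs, and the SD of the log2 ratio per intron was 0.456, 0.546, 0.547 and 0.895 in the same order. Of the unannotated sites of technical library 1, 31.8% (31.2 to 32.4) were found in technical library 2, 39.3% in the deeper first prp8-N1869D library, 39.4% in PRP8-WT, 39.7% in prp8-V1860N, 39.6% in prp8-V1860D and 45.1% in prp8-V1870N. These shares depend on the depth of the library searched. With each library searched thinned to 652680 lariat reads, an alternative chosen after seeing the data, they were 31.8% in technical library 2, 32.1% in the first prp8-N1869D library, 32.6% in prp8-V1870N, 27.2% in prp8-V1860D, 26.7% in prp8-V1860N and 23.8% in PRP8-WT, and thinned to equal unannotated reads 31.8%, 32.7%, 32.6%, 29.8%, 29.6% and 27.3%.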

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

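All tests in this part on the read pairs and denominators were chosen after the result was seen. The aberrant 5' splice site rate lay below PRP8-WT at 0.943 times in prp8-V1860N and 0.786 times in prp8-V1860D, and above it in prp8-N1869D (1.08), its second sample (1.13) and prp8-V1870N (1.06). It was picked out because the samples of one set of mutants lay on one side of PRP8-WT and those of the other set on the opposite side. The division of the mutants by mutated residue was made after the values were seen. The division is not kept in full under alternatives chosen after seeing the data. With at least 5 reads per site prp8-N1869D stood at 0.998, and its second sample and prp8-V1870N at 1.02 and 1.02. With all lariat reads as denominator prp8-V1870N stood at 0.988 and the prp8-N1869D samples at 1.01 and 1.06. Without the 5 introns with the most aberrant reads both prp8-N1869D samples stood at 1.0. The values of prp8-V1860N, prp8-V1860D and prp8-V1870N were then 0.998, 0.835 and 1.11. The difference was not tested, and each mutant other than prp8-N1869D has 1 library.

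The ratio of all unannotated to annotated reads was higher in prp8-N1869D and prp8-V1870N than in PRP8-WT. If read pairs that are not lariats made the excess, most of it should lie in pairs over 1000 nt apart or in mitochondrial DNA. Mitochondrial pairs also include lariats of group II introns, so this class is not free of lariats. Distant and mitochondrial pairs held 48.9% of the excess in the second prp8-N1869D sample, the lowest value, and 65.9% in prp8-V1870N, so this source cannot be told apart from true lariats. A smaller denominator of ribosomal protein lariats is a candidate explanation for another part: with introns of other genes alone as denominator, the folds were 1.19 and 1.097 in the prp8-N1869D samples and 1.35 in prp8-V1870N, below 1.1 in 1 sample and above 1.2 in another, so it cannot be told apart either. The fold with that denominator was not computed for prp8-V1860N and prp8-V1860D. A difference in spliceosome fidelity between the strains stays open and untested.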

How the results depend on the processing

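No paired analysis was possible because the comparisons come from no test and PRP8-WT and each mutant other than prp8-N1869D have 1 library, with no labels that pair the samples. Alternatives chosen after seeing the data were leaving out mirror images, distant pairs or the 5 introns with the most aberrant reads, the minimum of 20 aberrant reads, leaving out the RPS21B position from the GT share, thinning of the library searched for shared sites, all those for the aberrant 5' splice site rate, and leaving out technical libraries for sites, locations, sequences and ratios per gene. Values are in the order prp8-V1860N, prp8-V1860D, prp8-N1869D, its second sample and prp8-V1870N where 5 are given, and prp8-N1869D, its second sample and prp8-V1870N where 3 are given. The fold of unannotated over annotated reads stayed above PRP8-WT in all alternatives run: with at least 2 reads per site 1.41, 1.45 and 1.52, with at least 5 reads 1.08, 1.13, 1.38, 1.43 and 1.50, with all lariat reads as denominator 1.39, 1.41 and 1.46 and prp8-V1860D at 1.13, without the 5 genes with the most reads 1.56, 1.60 and 1.65, as the median per gene 1.40, 1.25 and 1.35 and prp8-V1860D at 1.09, without sites within 10 nt of an annotated intron 1.53, 1.58 and 1.63, without mirror images 1.18, 1.27, 1.75, 1.81 and 1.97, and without distant and mitochondrial pairs 1.05, 1.02, 1.27, 1.29 and 1.22. Leaving out a technical library gave 1.46 to 1.57. The aberrant 5' splice site rate was less stable. With at least 2 reads per site the second sample stood at 1.09, with at least 5 reads prp8-N1869D turned to 0.998 and the second sample and prp8-V1870N stood at 1.02 and 1.02, with all lariat reads prp8-V1870N turned to 0.988 and the prp8-N1869D samples stood at 1.01 and 1.06, without the 5 genes with the most reads prp8-N1869D stood at 1.12, and without the 5 introns with the most aberrant reads the values were 0.998, 0.835, 1.0, 1.0 and 1.11. The number of unannotated sites was below PRP8-WT without thinning except in prp8-V1870N, at 0.860, 0.836, 0.732, 0.780 and 1.098, and with at least 2 reads at 0.807, 0.798, 0.632, 0.686 and 0.961, where by construction the deeper PRP8-WT library finds more sites; thinned with at least 2 reads it was 1.12 in prp8-V1860N and 1.44, 1.41 and 1.54, and without a technical library 1.37 to 1.52. The share in genes without introns, in points above PRP8-WT, was 2.95 in the second sample and 3.44 in prp8-V1870N by reads, and with at least 2 reads -0.0666 in prp8-V1860D and 2.86, 3.03 and 3.51, and 3.36 to 4.53 without a technical library. The GT share by reads was -3.51, -8.06, -2.12, -2.94 and -6.00 points, turned in prp8-V1860N and both prp8-N1869D samples, by reads without the RPS21B position -0.0775, -0.928, -0.330, -0.235 and -1.26, with at least 2 reads it was 2.85 in prp8-V1860D, with at least 5 reads 0.545 in prp8-N1869D, -0.00855 in its second sample and 1.93 in prp8-V1870N, and without a technical library 6.04 to 6.25. With median-of-ratios size factors the ribosomal protein introns of prp8-V1860D turned to 0.0126, and the snoRNA host list of the second sample stood at 0.292 without technical library 1 and turned to -0.0174 without library 2. The list of genes with 2 introns stood at 1.24 in the second sample without technical library 1 and at 0.832 without library 2, beside 0.758 with both. The median ratio per gene with at least 20 aberrant reads was 0.0072 in prp8-V1860N, -0.45 in prp8-V1860D and 0.24 in prp8-N1869D. Over the 252 genes taken without this limit, the second sample stood at 0.74 to 0.74 without a technical library, beside 0.18 with both. With at least 20 aberrant reads per intron, the median aberrant ratio of other introns turned from 0.42 to -0.595 in prp8-N1869D and from 0.44 to -0.261 in prp8-V1860D, that of snoRNA host introns to -0.0249 in prp8-V1860N and -0.0665 in prp8-V1860D, that of genes with 2 introns to -0.101 and -0.551 in the same strains, that of the actin list to -0.0575 in prp8-V1860D, and that of the biogenesis list to -0.178 in prp8-N1869D and -0.403 in prp8-V1860D. The number of higher and lower genes was 139 and 113 in prp8-V1860D without that limit and 39 and 67 with it. For the technical pair and each technical library against the first sample, correlations over sites were -0.116, -0.0942 and -0.127 by ranks, 0.991, 0.948 and 0.954 on linear counts, 0.981, 0.982 and 0.981 for annotated sites, 0.502, 0.530 and 0.504 for unannotated ones and 0.918, 0.917 and 0.910 with at least 5 reads. Overlap of technical library 1 with library 2 and with the first sample was 40.1% and 47.1% within 2 nt and 54.2% and 66.3% with at least 2 reads, and 32.1% with the first sample thinned to equal lariat reads and 32.7% to equal unannotated reads. The depth ratio was 5.48 with at least 2 reads. Except for the site numbers, the thinned overlap and the ratios per gene without a technical library, where depth differs by construction, the cause was not tested. Of the other values for the main comparisons, 71 moved by no more than the spread, without those of the gap between intron groups under another scaling, which cannot alter it.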

Other observations

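Several abundant lariats lay outside the intron table used here and are named after their values were seen; the tests of intron length, depth and the RPS21B reads were set before their results were seen. The one with the most reads summed over all libraries began at 383486 on chromosome VII, plus strand, with GTATGT, and had its main branch point at 383552 between annotated genes. It had 35.2 reads per 10000 annotated reads in PRP8-WT, 80.1 and 98.0 in the prp8-N1869D samples, 73.9 in prp8-V1870N, 38.8 in prp8-V1860N and 44.6 in prp8-V1860D. BDF2, a bromodomain protein gene annotated without an intron, had a GTAAGT at 331189 on chromosome IV joined to a branch point at 331277. Its values were 40.4 in PRP8-WT, 45.6 in prp8-V1860N, 31.8 in prp8-V1860D, 58.1 in prp8-N1869D, 53.4 in its second sample and 46.4 in prp8-V1870N. A site at 263109 on chromosome XII, plus strand, with GTACAT and a main branch point at 263357, had 1.03 in PRP8-WT and 6.40 in prp8-V1860N, 6.43 in prp8-V1860D, 8.17 and 8.85 in the prp8-N1869D samples and 15.8 in prp8-V1870N. This pair spans the annotated RPL22A 5' splice site at 263206 and ends inside that intron. It had 6991 reads over all libraries. A site at 691967 on chromosome II, plus strand, had 21053 and was lower in every mutant. Its values were 26.8 in PRP8-WT, 20.5 in prp8-V1860N, 16.6 in prp8-V1860D, 17.8 and 11.6 in the prp8-N1869D samples and 17.9 in prp8-V1870N.

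Mitochondrial group II introns, which are removed as lariats without the spliceosome, also gave reads in every library. The COX1 intron from 13987 to 16434 had its main branch position at 16428 and 2.80 reads per 10000 annotated reads in PRP8-WT, 3.18 in prp8-V1860N, 3.26 in prp8-V1860D, 2.10 and 1.53 in the prp8-N1869D samples and 2.17 in prp8-V1870N. The COX1 intron from 16471 to 18953 had 0.411 in PRP8-WT, 0.395 in prp8-V1860N, 0.510 in prp8-V1860D, 0.292 and 0.380 in the prp8-N1869D samples and 0.432 in prp8-V1870N, and the one from 25343 to 26228 had 0.105, 0.164, 0.103, 0.312, 0.217 and 0.161 in the same order, from 32 reads in PRP8-WT. The COB intron from 36955 to 37722 had 1.1996 in PRP8-WT, 0.882 in prp8-V1860N, 1.58 in prp8-V1860D, 1.03 and 0.941 in the prp8-N1869D samples and 1.32 in prp8-V1870N. All mitochondrial pairs together had 0.185 reads per 100 annotated reads in PRP8-WT, 0.289 in prp8-V1860N, 0.569 in prp8-V1860D, 0.407 in prp8-N1869D, 0.431 in its second sample and 0.717 in prp8-V1870N.

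Introns outside ribosomal protein genes took a larger share in prp8-N1869D and prp8-V1870N than in PRP8-WT, by a gap of 1.23 and 0.69 on the log2 scale. After thinning to equal annotated reads 95.4% of the gap was left in prp8-N1869D, which argues against low counts or the pseudocount as its source. Random thinning hardly alters shares of reads, so it cannot decide whether depth acted in another way. Lariat length is a candidate explanation, since among introns of 200 to 500 nt the gap was -19.1% of the full one in the first prp8-N1869D sample and -19.0% in the second. That comparison has 18 other introns against 97. Of the 97 ribosomal protein introns, 25 and 16 were higher than in PRP8-WT in the prp8-N1869D samples. Among them was RPS24A, with 423 nt, at 1.62 and 1.98, against the direction of length. At 500 to 2000 nt, with 5 other introns against 4, the others lay higher in both prp8-N1869D samples. Whether length acted through the strain or through preparation of the libraries was not tested.

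Reads joining the RPS21B branch region to a position inside its intron were more frequent in every mutant library than in PRP8-WT. A reverse transcriptase jump between repeats that end before both positions would need matching bases there. Of these, 1 base matched, where at least 6 had been set as the mark of such a jump. Bases after both positions were not compared. Reads shared with another locus would need the 25 bases from the internal position elsewhere in the genome, and 0 other places had them at up to 2 mismatches. Reads shared with another locus are argued against, and a jump only for repeats that end before both positions. A strain variant against the reference, an RNA end or a ligation product at this place was not tested, so the source of these reads stays open.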
